A study of Mus musculus with 6 samples.

How the data were processed

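The series holds 6 bulk RNA-seq libraries of splenic Tregs of C57BL/6 mice, 3 of RORγt+ Tregs and 3 of CCR6+ RORγt− Tregs. The series description gives 500000 sorted cells without saying whether per library. Tregs were sorted by flow cytometry after enrichment of CD4+ cells, per the labels' protocols. Salmon 1.2.0, DESeq2 with no version and the build GRCm38 are named in the submitters' processing notes, without role or order. The aligned annotation, filters and import step are not given in the sources used here.

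The table deposited by the authors holds 1 signal value per gene and library, for 15944 genes, which are normalized counts to 2 decimals and not raw counts. From the values, the median ratio of a library to the gene's geometric mean was 1.003 in every library, as median-of-ratios scaling gives. Low values clustered at multiples of a step per library (0.82 to 1.24, the value of 1 read), with 51.1% to 69.5% of values up to 20 reads within 0.1 read of a whole number, so raw reads could not be recovered. The design fixed before the data were examined named a count-based test, and its fallback for normalized values was used instead. Dividing column totals by the step gave approximate depths of 10800000, 11300000 and 9230000 reads for RORγt+ replicates 1 to 3 and 11200000, 12600000 and 14500000 for RORγt− replicates 1 to 3. A gene near 1 normalized count rests on about 1 read, so folds of low genes are imprecise. Genes listed at 0 in every library of a group are described as such and no fold is given against them. Genes at 0 in only some libraries of a group, such as Sostdc1 and Il23r, keep their fold changes.

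Values were analysed as log2(value + 1), with no filter, since every gene passed a mean of 1, with limma 3.58.1 in R 4.3.3 (linear model on the group, empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are on the log2(value + 1) scale, RORγt+ minus RORγt−, and understate changes of low genes. The fit had 4 residual and 3.43 prior degrees of freedom. A set of 31 gene lists, fixed from textbook knowledge before the data were examined, was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera and an estimated correlation, and with fry. Some genes belong to several lists. Gene symbols and positions came from GENCODE release M21 (GRCm38), in which 15851 of the 15944 gene identifiers were found. The share of a gene's 31-base sequence windows found in transcripts of other genes was computed for the called and named genes, on both strands.

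The genes named were taken, by a rule fixed beforehand, from the sort markers, the 12 largest changes in each direction among named genes past the threshold with a mean of at least 5 and no overlap between groups, up to 4 members per biological list by adjusted p, up to 2 abundant members of each quality or other-cell list, and members needed to say which rose or fell. Others are said to be chosen later, and some results that the rule covers are not reported here. The fit was tested on simulated counts for the 15944 genes with a spread pooled over both groups. For the comparison of the groups, 96 of 100 genes changed 4-fold and 36 of 100 changed 2-fold were recovered, all in the right direction, with 5 false calls among 137. With no gene changed, 0 genes and 0 of 31 random lists were called, and 4.83% of genes had an unadjusted p under 0.05. The simulated genes varied independently and no library stood apart. Error rates for lists of correlated genes or with an outlying library were therefore not tested.

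The alternatives tried were other pseudocounts, scalings and filters, a cut on fold change, a replicate block, each library left out, other list tests and, chosen after seeing the data, array weights, robust variances, quantile normalization, a mean of at least 10, and a correction for GC content and transcript length.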

Results

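RNA was sequenced in bulk from regulatory T cells (Tregs, CD4+ T cells that express the transcription factor Foxp3 and restrain immune responses) sorted from the spleens of C57BL/6 mice. Fluorescent reporters of Foxp3 and of RORγt, a transcription factor, and staining for the chemokine receptor CCR6 defined the sorts. The first group held Tregs positive for the RORγt reporter and the second held Tregs negative for it but positive for CCR6, with 3 libraries in each. Values for 15944 genes were given as normalized counts. Column totals lay between 11325902 and 11890770 normalized counts, and the value of a single read put the depth at about 9230000 to 14500000 reads per library. RORγt+ replicate 3 was the shallowest, with 1247 genes listed at 0 against 438 to 638 in the other 5 libraries. The labels do not tie the libraries to separate animals, so p-values measure the spread between these libraries, which may be technical.

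The comparison asked how Tregs that express RORγt differ from Tregs that carry CCR6 without it. Genes used in the sort were read first. Ccr6 (chromosome 17, 8236043 to 8257141, GRCm38) was higher in RORγt+ Tregs, at 804 ± 101 against 134 ± 19.8 normalized counts (SD, n = 3), although CCR6 was a gate of the other sort only. Its log2 fold change was 2.58 ± 0.18 (SE, adjusted p = 0.00554), and its call was lost without RORγt+ replicate 2 (adjusted p = 0.0561). Foxp3 stood at 11505 ± 963 and 9963 ± 203 normalized counts in the RORγt+ and RORγt− sorts (adjusted p = 0.595), and 26.4% of its sequence windows also occur in transcripts of other genes. Cd4 (adjusted p = 0.911) and Cd3e (adjusted p = 0.925) did not pass the test either, and the signs of their fold changes turned when certain libraries were left out.

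**Figure D1:**
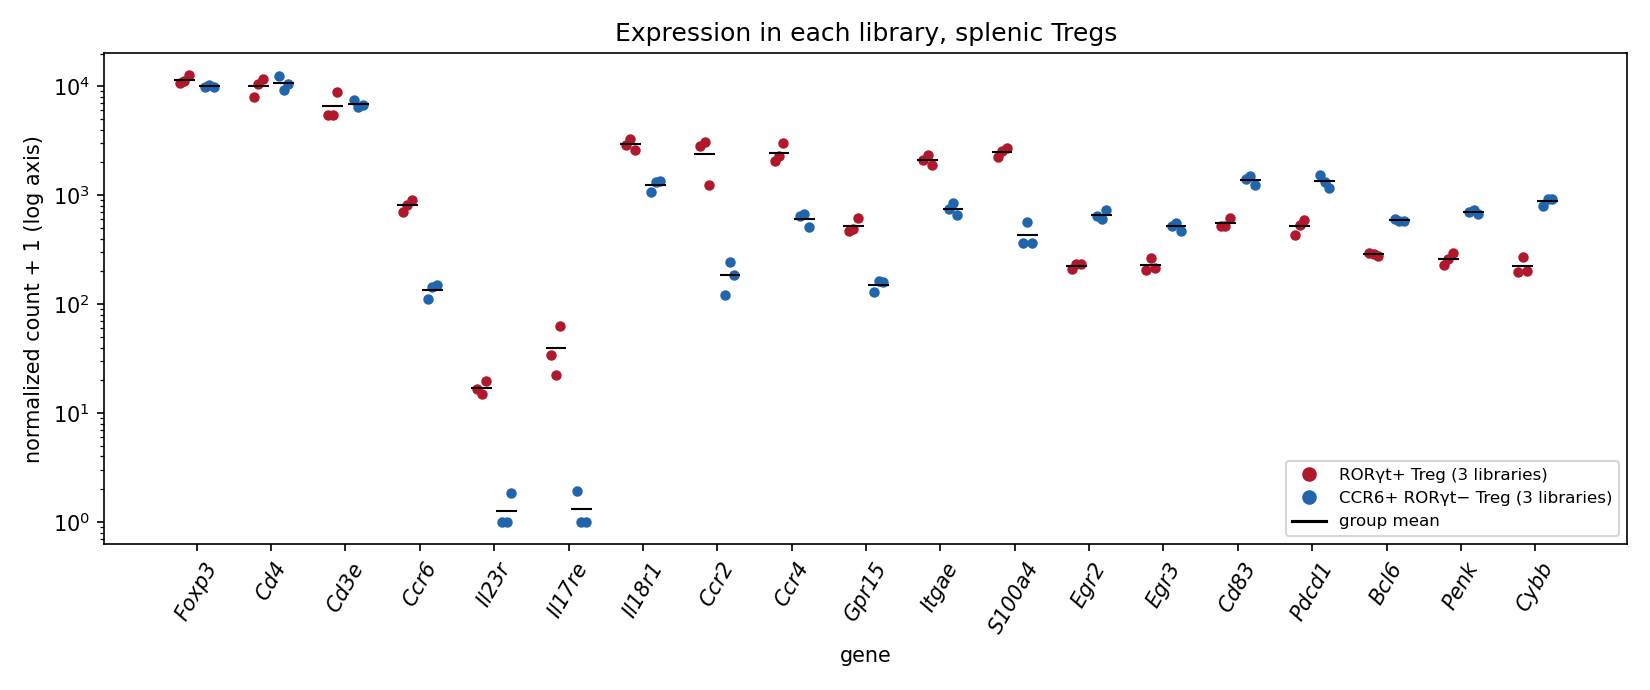
Normalized counts plus 1 (log axis) of 19 genes in each of the 6 libraries, with 3 RORγt+ libraries in red, 3 CCR6+ RORγt− libraries in blue and the group mean as a black line. Ccr6 lies between 698 and 900 normalized counts in the RORγt+ libraries and between 112 and 148 in the others, while the Foxp3 values of both groups lie within 9790 to 12609.

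Limma with a mean-variance trend called 90 genes at a Benjamini-Hochberg adjusted p under 0.05, 51 higher and 39 lower in RORγt+ Tregs, and 1741 genes had an unadjusted p under 0.05. The groups did not overlap in any of the 90 genes, and did not overlap in 18.1% of all genes, where chance gives 10%. The largest increases in named genes included Il17re, a subunit of an IL-17 family receptor (38.7 ± 20.7 against 0.307 ± 0.531 normalized counts, SD, n = 3), and the membrane metalloproteinase Mmp25 (271 ± 38.1 against 11.3 ± 9.91). Plekhf1, Popdc2, the leukotriene B4 receptor Ltb4r1, Il23r, Ccr2 and the guanylate-binding protein Gbp2b also rose, with log2 fold changes of 3.61 to 4.48 and adjusted p of 0.00778 to 0.0361. Olfr60 was listed at 0 in all 3 RORγt− libraries and averaged 29.8 ± 19.3 in the RORγt+ libraries. The largest decrease was in Sostdc1, a secreted antagonist of BMP and Wnt signalling, at 1.32 ± 2.29 against 129 ± 40.5 normalized counts (log2 fold change −6.20 ± 0.70, adjusted p = 0.0157). Art3, Ptpn5, Dnase1l3, Ier5l, Ecel1, Slc24a3, Noxa1, the histone deacetylase Hdac9, Fam160a1 and Dscam fell by 2.32 to 3.67 on the log2 scale (adjusted p between 0.00951 and 0.0367). Exosc6 was listed at 0 in every RORγt+ library and averaged 57.9 ± 11.4 in the RORγt− libraries, but all of its sequence windows also occur in Aars, whose values did not pass the test (adjusted p = 0.835), so its call is uncertain. All 90 genes kept their direction in each of the 6 fits that left out a library, which groups without overlap make certain. Only 1 of them kept its call in all 6. The count of calls was 4 without RORγt+ replicate 1, 4 without replicate 2 and 174 without replicate 3, and 8, 10 and 7 without RORγt− replicates 1, 2 and 3. Counts of calls within gene lists rest on these same calls.

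Of 22 measured members of the type 17 programme, 8 rose in RORγt+ Tregs, none fell and 14 did not pass the test, and 13 rose and 1 fell when p-values were adjusted over the list alone. Besides Ccr6, Il17re and Ltb4r1, the members that rose included Tmem176a, Il23r (16.1 ± 2.48 against 0.277 ± 0.479 normalized counts, SD, n = 3), the IL-18 receptor subunit Il18r1 (2924 ± 325 against 1250 ± 165) and the chemokine receptor Cxcr6. The IL-1 receptor Il1r1 (adjusted p = 0.0617) and the aryl hydrocarbon receptor Ahr (adjusted p = 0.0617) had log2 fold changes of 3.90 and 1.19 without passing the threshold, and were chosen after their values were seen. The list's median log2 fold change was 1.21, and camera with its preset correlation gave an adjusted p of 5.15e-11. With an estimated correlation the adjusted p was 0.133, and none of the 31 lists passed in that test.

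In the list of chemokine receptors, which steer T cell migration, 5 of 21 measured members rose, none fell and 16 did not pass. Ccr6, whose protein gated the other sort, was among the 5. The list also holds S1pr1, S1pr4 and Gpr183, which are not chemokine receptors and had log2 fold changes of 0.46, 0.61 and 0.60. Adjusted over the list alone, 13 rose and 2 fell. Ccr4 averaged 2453 ± 481 against 610 ± 83.5 normalized counts (SD, n = 3, adjusted p = 0.0095). Ccr2 averaged 2406 ± 1009 against 183 ± 62.5 (3.66 ± 0.40, adjusted p = 0.0139), and Gpr15, a receptor known for homing to the large intestine, 524 ± 78.3 against 150 ± 18.6 (1.79 ± 0.18, adjusted p = 0.0136). Gpr15 shares 10.8% of its sequence windows with the neighbouring gene Cpox. Ccr8, at a log2 fold change of −1.21 ± 0.20, missed the threshold (adjusted p = 0.0593). The median over the list was 0.61, with a camera adjusted p of 1.83e-07 and an adjusted p of 0.133 with an estimated correlation.

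The list of effector Treg activation genes split, with 5 members higher, 2 lower and 21 not past the threshold of 28 measured. Adjusted over the list alone, 10 rose and 6 fell. The calcium-binding proteins S100a4 (2518 ± 244 against 431 ± 120 normalized counts, SD, n = 3, adjusted p = 0.00613) and S100a6, the galectins Lgals1 and Lgals3, and the integrin Itgae, which binds E-cadherin on epithelium (2109 ± 222 against 752 ± 98.4, adjusted p = 0.012), rose. Egr2 and Pdcd1 fell. Of the S100a4 windows, 49.2% also occur in an overlapping gene model, Gm42674, which averaged 9.89 and 4.62 normalized counts. The camera test on this list did not pass (adjusted p = 0.133), nor with an estimated correlation (adjusted p = 0.586). Of 17 members of the tissue Treg and repair list, Itgae rose and Penk, which encodes proenkephalin, fell (261 ± 32.8 against 697 ± 29.3, adjusted p = 0.0136), and 15 did not pass; 10.9% of the Penk windows occur in another gene. Adjusted over the list alone, 3 rose and 5 fell there, and camera gave an adjusted p of 0.47. Of 26 integrin and adhesion genes, Itgae rose, Epcam fell and 24 did not pass, with 3 higher and 1 lower adjusted over the list alone. Camera gave that list an adjusted p of 0.191, and 0.0497 without RORγt+ replicate 3.

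In the list of T cell receptor signalling and immediate early genes, 2 of 25 measured members fell in RORγt+ Tregs, none rose and 23 did not pass, with 5 lower adjusted over the list alone. The members that fell were the transcription factors Egr2 (log2 fold change −1.55 ± 0.15, SE, n = 3 per group, adjusted p = 0.00961) and Egr3 (228 ± 31.6 against 517 ± 43.7, −1.18 ± 0.17, adjusted p = 0.0329). Fosb, at −2.12 ± 0.35, did not pass (adjusted p = 0.0593). Camera gave the list an adjusted p of 0.000308, and the adjusted p was 0.283 with an estimated correlation. Heat shock and sort stress genes pointed down as well (camera adjusted p = 1.37e-05, and 0.33 with an estimated correlation). The cause of either fall was not tested. Of 14 T follicular genes, Pdcd1, which encodes the inhibitory receptor PD-1 (517 ± 78.4 against 1346 ± 192 normalized counts, adjusted p = 0.0219), and Bcl6, the transcription factor of follicular T cells (286 ± 7.48 against 587 ± 13.9, adjusted p = 0.0224), fell and 12 did not pass. Adjusted over the list alone, 1 rose and 5 fell, and camera gave an adjusted p of 0.000308, with 0.283 as the adjusted p with an estimated correlation. Of 9 markers linked to thymic-origin Tregs, Cd83 fell (550 ± 53.4 against 1379 ± 123, adjusted p = 0.0136) and 8 did not pass, with 4 lower adjusted over the list alone. Nrp1, a surface marker of that list, stood at 1904 ± 411 against 3482 ± 126 (limma adjusted p = 0.101, and 0.0253 without RORγt+ replicate 3). Ikzf2, another member, was named after its values were seen. Its log2 fold change was −0.69 (adjusted p = 0.738), and 0.020 without RORγt+ replicate 3 (adjusted p = 0.969). The camera adjusted p of 0.00548 for these markers rose to 0.0604 without RORγt+ replicate 3, and was 0.283 with an estimated correlation. Of 25 costimulation and checkpoint genes only Pdcd1 passed, and 3 rose and 7 fell adjusted over the list alone. Camera gave that list an adjusted p of 0.0844, which was 0.0438 without RORγt+ replicate 3 and 0.0405 without RORγt− replicate 3.

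**Figure D2:**
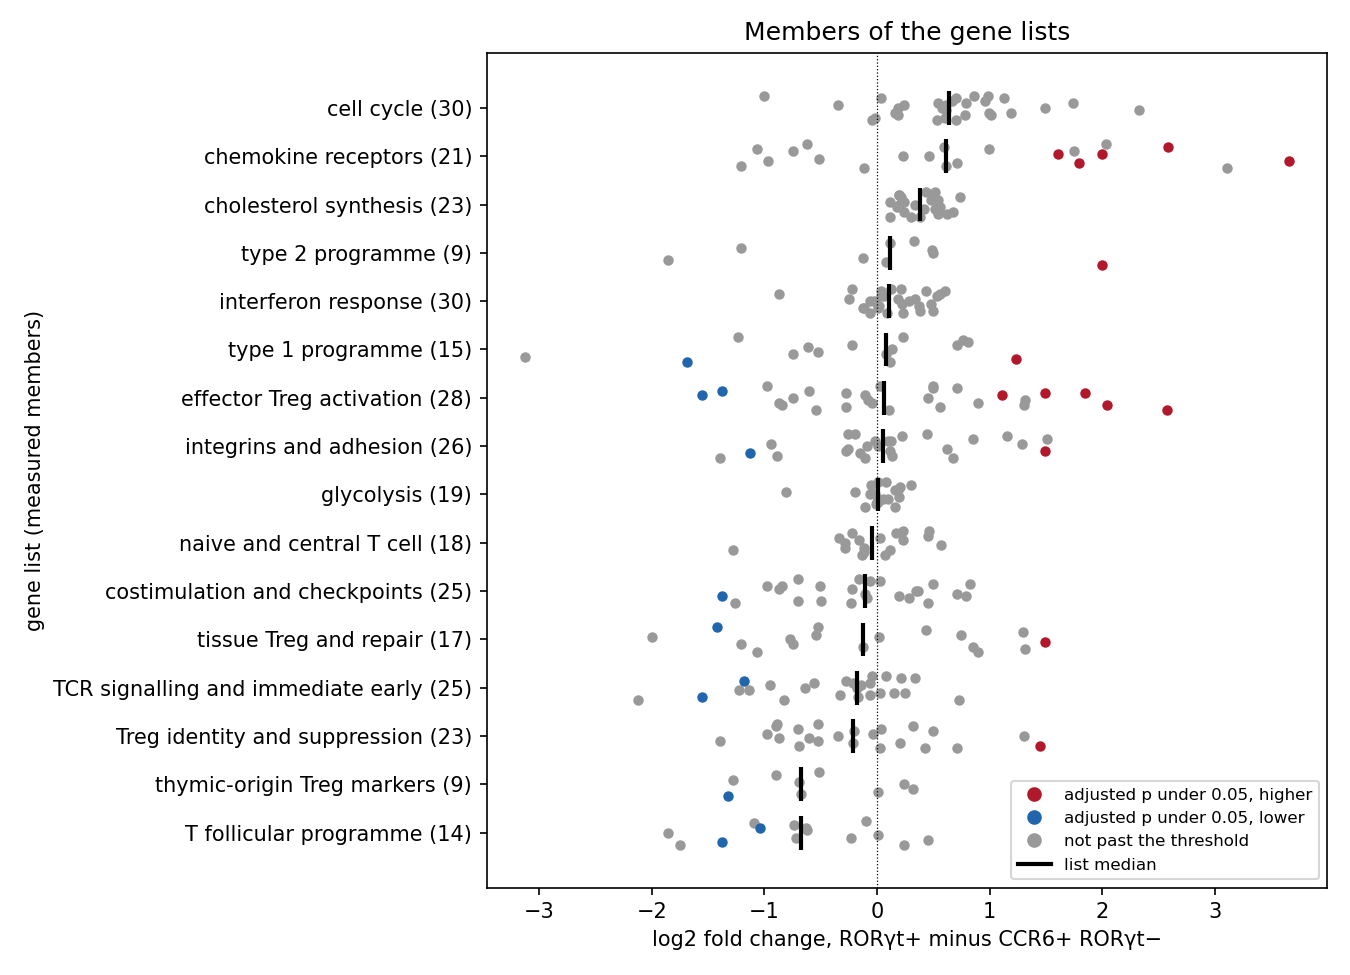
Log2 fold change (RORγt+ minus CCR6+ RORγt−, horizontal axis) of each measured member of the biological gene lists other than the type 17 programme (vertical axis, number of members in parentheses), coloured by whether it passed an adjusted p of 0.05, with the list median as a black line. The cell cycle list has the highest median of those shown, 0.637, and the T follicular list the lowest, −0.674.

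Several lists passed the camera test with its preset correlation, and not with an estimated one, while no member passed the threshold over all genes. By fry the adjusted p was 0.0321 for cholesterol synthesis, 0.112 for cell cycle and 0.124 for interferon response genes. Cholesterol synthesis genes had a median log2 fold change of 0.382 over 23 measured members (camera adjusted p = 9.23e-08, adjusted p = 0.244 with an estimated correlation), and Insig1 and Sqle had values of 0.56 and 0.62. Cell cycle genes had a median of 0.637 over 30 members (camera adjusted p = 9.34e-07, adjusted p = 0.283 with an estimated correlation). Adjusted over the list alone, 2 cell cycle genes rose, and Rrm2, a subunit of ribonucleotide reductase, stood at 174 ± 13.4 against 75.7 ± 7.23 normalized counts (SD, n = 3, adjusted p = 0.0593). Interferon response genes had a median of 0.107 over 30 members (camera adjusted p = 0.0186, adjusted p = 0.33 with an estimated correlation), and the camera value was 0.103 without RORγt+ replicate 2 and 0.0632 without RORγt− replicate 2. No member of the cholesterol or interferon lists passed when adjusted over the list alone. Of 23 genes of Treg identity and suppression, the cytokine signalling inhibitor Socs2 rose (842 ± 24.2 against 311 ± 53.6, adjusted p = 0.0157) and 22 did not pass, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.279). Of 15 type 1 genes Il18r1 rose and the chemokine Ccl5 fell (97.1 ± 20.6 against 315 ± 67.3, adjusted p = 0.0361), with 2 higher and 3 lower adjusted over the list alone. The median of that list was 0.0771 while its mean was −0.274 and camera pointed down (adjusted p = 0.73). Of 9 type 2 genes Ccr4 rose, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.308). Glycolysis genes (19 members, camera adjusted p = 0.66) and genes of naive and central T cells (18 members, camera adjusted p = 0.993) had no member past the threshold over all genes, and adjusted over the list alone 0 glycolysis genes passed and 1 gene of naive and central T cells fell.

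Markers of other cells and signs of RNA quality were read in the same way. The list of γδ T cell and innate type 17 markers moved with the type 17 genes, with 2 of 11 measured members higher, 5 higher adjusted over the list alone and a camera adjusted p of 9.2e-05 (adjusted p = 0.283 with an estimated correlation). The members that rose were Il23r, which is also in the type 17 list, and 5830411N06Rik (79.2 against 0.207 normalized counts, adjusted p = 0.00859). The call of Il23r was lost in each of the 6 fits that left out a library (adjusted p between 0.0599 and 0.169). The γδ receptor constant gene Trdc stood at 99.2 against 61.6 normalized counts (log2 fold change 0.69 ± 0.24, SE, adjusted p = 0.354). Its groups did not overlap, as in 18.1% of all genes, and it was among the 5 members higher adjusted over the list alone. Kit, Cd163l1, Zbtb16, Blk and Il7r had log2 fold changes of 2.40, 2.30, 0.93, 0.70 and 0.45 and did not pass over all genes. The γ chain constant genes Tcrg-C1, Tcrg-C2 and Tcrg-C4, named after their values were seen, had log2 fold changes of −0.024, −0.24 and −0.56 and did not pass, and those of Tcrg-C1 and Tcrg-C2 were 0.046 and 0.087 without RORγt+ replicate 3. CD8 T cell markers pointed down (camera adjusted p = 0.0186, and 0.118 without RORγt− replicate 2; adjusted p = 0.283 with an estimated correlation), with Ccl5 the 1 member of 5 past the threshold and 3 lower adjusted over the list alone, while Cd8b1 stood at 117 ± 13.9 against 108 ± 10.8. Of 14 monocyte and macrophage markers, Cybb, a subunit of the phagocyte oxidase, fell (223 ± 40.1 against 881 ± 72.4, adjusted p = 0.00859) and 13 did not pass. The median log2 fold change of that list was nonetheless 1.08, and camera pointed up (adjusted p = 0.421). Camera gave no call for markers of B cells (adjusted p = 0.206, and 6.62e-05 without RORγt− replicate 2), neutrophils (0.0998), dendritic cells (0.869), NK cells (0.322), NKT and MAIT cells (0.66), or red cells and platelets (0.433, and 0.0123 without RORγt− replicate 1). Median log2 fold changes were 0.646 for B cell, 1.35 for neutrophil, 0.897 for NK and 0.237 for NKT and MAIT markers. They were −0.322 for dendritic cell and −0.287 for red cell and platelet markers. The camera tests compare the groups and do not show that such transcripts were absent or equally abundant. The B cell marker Ighm averaged 7539 and 8216 normalized counts in the RORγt+ and RORγt− sorts, and Cd74 averaged 700 and 763. Plasma cell markers had a camera adjusted p of 0.0572, which was 0.0179 without RORγt+ replicate 3 and 0.002 without RORγt− replicate 2. Hba-a2, a haemoglobin gene, reached 3097 normalized counts in RORγt− replicate 2 against 35.4 to 608 in the other 5 libraries. Mitochondrially encoded genes took 4.29% ± 0.46 of the normalized counts in RORγt+ libraries and 5.83% ± 0.69 in RORγt− libraries (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Camera pointed down for these genes (adjusted p = 1.59e-09), for ribosomal protein genes (1.52e-06) and for heat shock and sort stress genes (1.37e-05), none of which passed with an estimated correlation (adjusted p = 0.283, 0.441 and 0.33). No member of these 3 lists passed over all genes, and adjusted over the list alone 7 mitochondrial genes fell. The list of 7 sort markers had a camera adjusted p of 0.0166, which was 0.501 without RORγt+ replicate 3 and 0.397 with an estimated correlation, and its median of −0.00259 lay below 0 while its mean lay above 0. RORγt+ replicate 3 stood apart, with correlations to the other libraries of 0.932 to 0.939 on the log2 scale against 0.947 to 0.967 among the other 5. Without it the count of calls was 174, with 84 of the 90 genes among them.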

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

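The array weights, robust variances, quantile normalization, mean filter and correction for GC content and length were chosen after seeing the data; the other alternatives were planned. TMM and median-of-ratios factors, count-based tests, voom and a count filter were not run, because the values are not counts; a filter at a mean of 1 removes no gene. With pseudocounts 0.1 and 5, upper-quartile scaling, library totals, a cut at an absolute log2 fold change of 1, 1 CPM of the column total in 3 libraries, a mean of 10, robust variances and quantile normalization, between 84 and 103 genes passed. Array weights gave 358 genes (170 higher, 188 lower), with all 90 among them, and gave RORγt+ replicate 3 a weight of 0.199. The correction for GC and length gave 136 genes (66 lower), with 86 of the 90 among them; the cause was not tested. Leaving out 1 library gave 4 to 174 calls, 1 to 85 higher and 0 to 89 lower, and between 1 and 2 of the 5 sort markers of the naming rule, a smaller set than the list of 7; the cause was not tested. With a replicate block the counts were 1 gene, 1 higher and 0 lower (1130 genes at an unadjusted p under 0.05), and 1 sort marker. Same-numbered libraries deviated from their group means with correlations of −0.2, −0.06 and −0.36, and no library correlated best with its own number. These values gave no sign that the numbers pair the libraries. They cannot rule out a shared animal, pool or day, because the deviations also went with each library's trend with GC content. RORγt+ replicate 3 and RORγt− replicate 1, with rho of 0.56 and 0.44 with GC content, correlated at 0.27. All 14 called lists passed under the block too. Of the 31 lists, 14 passed, 0 with an estimated correlation and 7 with fry. Fry passed type 17, chemokine receptor, T follicular, cholesterol synthesis, CD8, γδ and sort marker lists (adjusted p between 0.00233 and 0.0321). It did not pass the lists of T cell receptor signalling (0.0576), thymic-origin markers (0.089), cell cycle (0.112) and interferon response (0.124). Nor did the mitochondrial (0.0616), heat shock (0.184) and ribosomal (0.256) lists pass by fry. Among the lists of other cells and RNA quality 5 passed, 0 with an estimated correlation and 2 with fry. The call of the CD8 list was lost with the filter at 1 CPM (adjusted p = 0.0865) and at a mean of 10 (0.0897), and that of the sort marker list with array weights (0.196). The scalings moved the median log2 fold change of all genes by under 0.1.

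None of the called genes covered by the naming rule and none of the called lists turned direction under these alternatives. For these genes the fits without 1 library could not turn it, since their groups did not overlap. Values that had not passed turned as follows. Log2 fold changes over the fits without 1 library ran from −0.22 to 0.049 for Cd4, −0.34 to 0.017 for Cd3e, −0.25 to 0.15 for Rplp0, −0.34 to 0.18 for Cd74, −2.58 to 1.05 for Igha, −0.42 to 0.16 for Bst2, −1.704 to 1.502 for Hba-a2 and −1.78 to 1.397 for Hbb-bs. Rplp0 was −0.046 with upper-quartile scaling and −0.20 with array weights, Igha 0.58 with array weights and Bst2 0.013 with the correction for GC and length. Camera turned its direction for some uncalled lists, with adjusted p of 0.985 (pseudocount 0.1), 0.859 (library totals) and 0.944 (GC and length) for naive and central T cells, 0.967 for tissue Treg and 0.304 for glycolysis (array weights). The filter at 1 CPM gave 0.387 for monocyte and 0.768 for NKT markers, and the mean of 10 gave 0.625 for monocyte, 0.853 for NK and 0.759 for NKT markers. Without 1 library the adjusted p ran from 0.575 to 0.954 for naive and central T cells, 0.292 to 0.854 for tissue Treg, 0.501 to 0.986 for type 1, 0.0604 to 0.996 for glycolysis, 0.565 to 0.991 for dendritic cell and 0.0123 to 0.916 for erythroid markers. The cause was not tested. Depth limits genes near 1 read, about 0.82 to 1.24 normalized counts.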

Other observations

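Genes chosen after their values were seen add to the picture. RORγt+ Tregs had more Ikzf3, which encodes the transcription factor Aiolos (4601 ± 425 against 2566 ± 90.8 normalized counts, SD, n = 3, limma adjusted p = 0.0313), more of the lysosomal protease Lgmn (363 ± 31.7 against 110 ± 13.7, adjusted p = 0.0136) and more of the water and glycerol channel Aqp3 (179 ± 70.1 against 33.1 ± 9.05, adjusted p = 0.0359). The calcium pump Atp2b4 (490 ± 133 against 2346 ± 76.0, adjusted p = 0.00951), the prostaglandin E2 receptor Ptger2 (log2 fold change −1.12 ± 0.14, SE, adjusted p = 0.0222) and Tbc1d4, a regulator of glucose transporter trafficking (1568 ± 125 against 3044 ± 210, adjusted p = 0.0222), were lower. Each of these calls passed in 1 of the 6 fits that left out a library, with highest adjusted p of 0.0847 to 0.206.

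The test of the whole effect of GC and length was chosen after the result was seen. The libraries compared in the depth test were reworded after the pattern was known, before its ratio was computed, and the other tests were written first. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real split, which is the real split itself with 90 genes; the highest other split gave 3. That other split, RORγt+ replicates 1 and 2 with RORγt− replicate 3 against the rest, had 1955 genes at an unadjusted p under 0.05, against 1741 in the real split. With 10 splits the share cannot fall under 0.05, so this test does not decide about chance.

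RORγt+ replicate 3 stood apart from RORγt+ replicates 1 and 2. Low depth is argued against by genes with a mean of at least 500, in which its SD from the other replicates was 1.997 times the highest among the RORγt− libraries. Its difference from replicates 1 and 2 rose with transcript GC content (Spearman rho 0.56 across genes, which are not independent replicates) and fell with transcript length (rho −0.323), which meets the bounds set beforehand for both, but RORγt− replicates 1 and 3, which did not stand apart, had rho with GC content of 0.44 and −0.457 against their own group. After a correction for both, taken from each gene's longest annotated transcript, the SD of replicate 3 fell from 0.683 to 0.516. The ratio was still 1.79, so these trends as measured did not account for the whole difference. A GC or length bias that this measure misses is not excluded. RNA quality or a biological difference between the sorted samples stays open and was not tested.

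Nr1d1, which encodes the clock repressor REV-ERBα, was chosen after its values were seen and stood at 366 ± 156 against 45.6 ± 4.91 normalized counts (SD, n = 3, log2 fold change 2.90 ± 0.31, limma adjusted p = 0.0136). Its end overlaps that of Thra on the other strand, which had an adjusted p of 0.541. A time-of-day difference between the sorts cannot be told apart from other causes: Dbp, Tef, Nr1d2, Per1, Per2 and Per3 had a median log2 fold change of 0.104. That lies under the bound of 0.5 set beforehand against this explanation, but the bound was set aside after the value was seen, because the genes peak at different times and went both ways (Dbp 0.59, Per1 −0.21), so a median does not decide.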
